A study of Mus musculus with 12 samples.

How the data were processed

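Total RNA was extracted with Trizol, labelled with biotin as cRNA by an Affymetrix protocol and hybridised to an Affymetrix array, per the labels' protocols. The deposited values are on a log2 scale, and RMA, a method of background correction, quantile normalization and probe summary, is the only processing named, per the submitters' processing notes, with no version given. The values ran from 2.14 to 13.9, and the medians of the 12 arrays lay within 0.0945 of each other. They were used as the authors deposited them. No scanner files were used here, so background and signal over background could not be examined, and whether the 1246 probe sets are the whole array is not given in the sources used here.

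Probe sets were named by the unversioned RefSeq accession in their names, through a table of mouse genes of assembly GRCm38.p6; no coordinates are printed, since the array's own build is not given. Of 1246 probe sets 963 matched 1 symbol each, for 909 symbols, of which 48 had more than 1 probe set. Another 261 carried UCSC-style names, 21 RefSeq names without a match and 1 another accession, and these stayed unnamed. The suffix of 275 probe sets marks probes shared between transcripts or similar sequences, Lgals3, Hs3st1 and Slc35f1 among them, so their signal may hold related transcripts. No 2 arrays held identical values.

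Samples were grouped by the tumour line and host genotype in their labels, 3 arrays to each of 4 groups. A model of 4 group means was fitted to all 12 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, so that all groups shared 1 estimate of spread with 8 residual and 2.39 prior degrees of freedom. From it came 7 comparisons: the tumour line difference (Tm1N3 minus Tm1G3) in each host, the host difference (knockout minus wild-type) in each line, both averages and the interaction. P values were adjusted by the Benjamini-Hochberg method over the 1246 probe sets of a comparison, with a threshold of 0.05. Fold changes are antilogs of log2 differences, and errors are SD for group levels and limma's moderated SE for differences. Lgals3 was also tested by two-sided exact permutation.

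The design, the alternatives and 25 gene lists were fixed before the data were examined. The 9 lists with at least 5 measured genes were galectins, endothelial markers, angiogenic factors, macrophage and monocyte markers, T and NK cell markers, neutrophil markers, cytokines and chemokines, fibroblasts and extracellular matrix, and cell adhesion. Another 28 lists, of glycan and signalling families, were drawn up after the array's gene names had been seen. Lists were tested on the brightest probe set per gene with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Camera compares a list only with the other genes of this focused array. No list passed fry after adjustment. None passed camera with an estimated correlation in any comparison either (smallest camera adjusted p = 0.724). The loss of a call under either setting thus does not tell lists apart. For galectins, endothelial, angiogenic, T and NK cell, fibroblast and adhesion lists with medians near 0, camera's direction differed in sign from the median in some comparisons, none of which passed.

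Genes named in the text are, per comparison, up to 12 on either side with the largest log2 difference among named probe sets past the threshold whose groups did not overlap, or the 5 with the smallest p where fewer than 5 passed, plus Lgals3 and up to 4 members of each fixed list. A gene that this rule takes in is not reported here. The further glycan and receptor genes named in the averaged line comparison also passed the threshold and were chosen after their values were seen.

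Replicate numbers in the labels are shared between groups. Deviations from group means of same-numbered arrays correlated, across probe sets, between 0.184 and 0.752 for the hosts of Tm1N3 tumours and between 0.249 and 0.308 for the hosts of Tm1G3 tumours. By the rule that every pair exceed 0.1, the numbers were taken to pair the arrays of the 2 hosts within a line. They did not pair the lines, where correlations ran from 0.00809 to 0.544 in wild-type and from -0.660 to 0.272 in knockout hosts. The pairing rests on these correlations, as the labels do not say what a number stands for. The titles also give each array a number of its own, and replicate numbers follow its order within each group. The labels thus give no sign of a pair of hosts. By best match, 4 of 6 arrays of the Tm1N3 and 6 of 6 of the Tm1G3 host comparison went with their own number. It was also 4 of 6 in the wild-type line comparison, taken as unpaired, so the rule is weak for Tm1N3.

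The procedure was tested on simulated data with 200 changed probe sets. In the wild-type line comparison over 1246 probe sets it called 76.1% of those changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 97.0% of those changed by 2, and 0.669% of 1046 unchanged ones. For the averaged line comparison over 1246 probe sets the shares were 86.6%, 100% and 98.5%, with 0.574% of unchanged ones. The simulated genes varied independently, so the shares are optimistic for these tumours, whose genes move together. With 200 changed probe sets the Benjamini-Hochberg cut-off is also more lenient than where few change. The shares thus do not hold for the comparisons with few calls or none.

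Alternatives were quantile normalization again, centring each array on its median, leaving out the lowest 25% of probe sets by mean level, eBayes with trend and robust settings, array weights, fitting only the arrays compared, replicate number as a block, 1 probe set per gene, and leaving out each array in turn. The macrophage marker mean as a covariate, leaving out the 2 arrays with the lowest mean correlation with the rest, a replicate block within each line, and arrays of the same number within a line as a random block (duplicateCorrelation of limma, correlation 0.273) or kept together in permutations and slopes were added after seeing the data.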

Results

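RNA from 12 mouse melanoma tumours was profiled on a focused Affymetrix array of genes for glycan synthesis, lectins, cytokines and growth factors. Wild-type mice and mice lacking galectin-3, a secreted and intracellular lectin encoded by Lgals3, were injected with 1 of 2 melanoma lines. The labels call Tm1N3 galectin-3 expressing and Tm1G3 galectin-3 silenced. The 4 groups of line and host held 3 arrays each, and the table gave 1246 probe sets per array, of which 963 carried 1 gene symbol. The series set out to separate galectin-3 made by the tumour cells from galectin-3 made by the host tissue in tumour growth. The number of arrays limits the precision of every value, and p-values measure only the spread between these samples, since the labels do not say in so many words that each replicate was a separate animal.

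The arrays were alike over all probe sets, with Pearson correlations across probe sets from 0.976 to 0.998 between any pair. The leading principal component held 37.2% of the variance, of which 7.93% lay between tumour lines and 1.51% between hosts. The next component held 19.2%, of which 88.4% lay between tumour lines and 0.861% between hosts. On it the 6 Tm1N3 arrays lay between 0.436 and 4.66 and the 6 Tm1G3 arrays between -4.29 and -2.04, so the lines did not overlap.

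**Figure D1:**
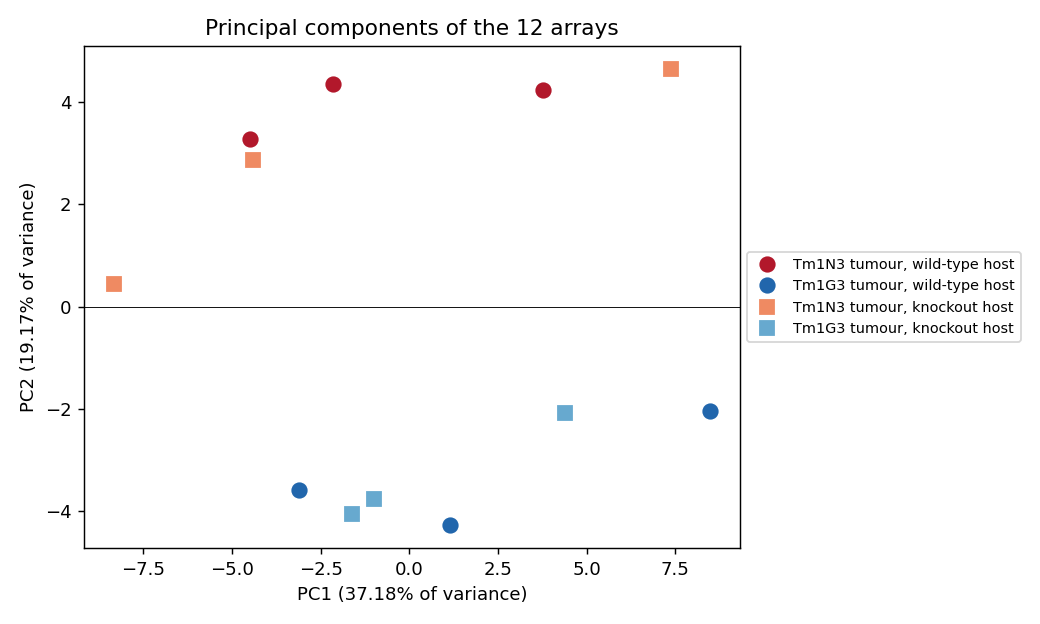
Scores of the 12 arrays on the first 2 principal components of the log2 RMA values, with the share of variance on each axis label, circles for wild-type and squares for knockout hosts, reds for Tm1N3 and blues for Tm1G3. The lines part along PC2, where the lowest Tm1N3 score was 0.436 and the highest Tm1G3 score was -2.04, while each group is spread widely along PC1.

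Lgals3, the gene that defines both factors, was measured by 1 probe set and stood high on every array, between the 85.2 and 94.9 percentile of probe sets. Its log2 level was 9.97 ± 0.37 (SD, n = 3) in Tm1N3 tumours of wild-type hosts and 9.61 ± 0.34 (SD, n = 3) in Tm1G3 tumours of wild-type hosts. In knockout hosts it was 9.86 ± 0.62 (SD, n = 3) in Tm1N3 tumours and 9.31 ± 0.43 (SD, n = 3) in Tm1G3 tumours. The Tm1N3 mean was thus the higher in both hosts, by 0.36 on the log2 scale in wild-type hosts and 0.55 in knockout hosts, but neither difference passed a test (two-sided exact permutation p = 0.3 in each, with 0.1 the smallest p that 3 against 3 arrays allow). With 1 array left out these differences ran from 0.15 (without WT_Tm1N3 replicate 3) to 0.54 (without WT_Tm1G3 replicate 3) in wild-type hosts and from 0.21 (without KO_Tm1N3 replicate 3) to 0.81 (without KO_Tm1N3 replicate 1) in knockout hosts. Averaged over hosts the difference was 0.46 with a 95% interval from -0.06 to 0.97. Between hosts Lgals3 differed by -0.11 in Tm1N3 tumours and by -0.30 in Tm1G3 tumours, knockout minus wild-type (two-sided exact permutation p = 0.8 and 0.4). The first turned to 0.10 without WT_Tm1N3 replicate 3 and 0.15 without KO_Tm1N3 replicate 1, and the other ran from -0.55 (without KO_Tm1G3 replicate 2) to -0.12 (without WT_Tm1G3 replicate 3). Where the probe set lies relative to the deleted part of the gene, to a silencing sequence or to a coding plasmid is not given in the sources used here, so these values neither bear out nor contradict the labels.

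**Figure D2:**
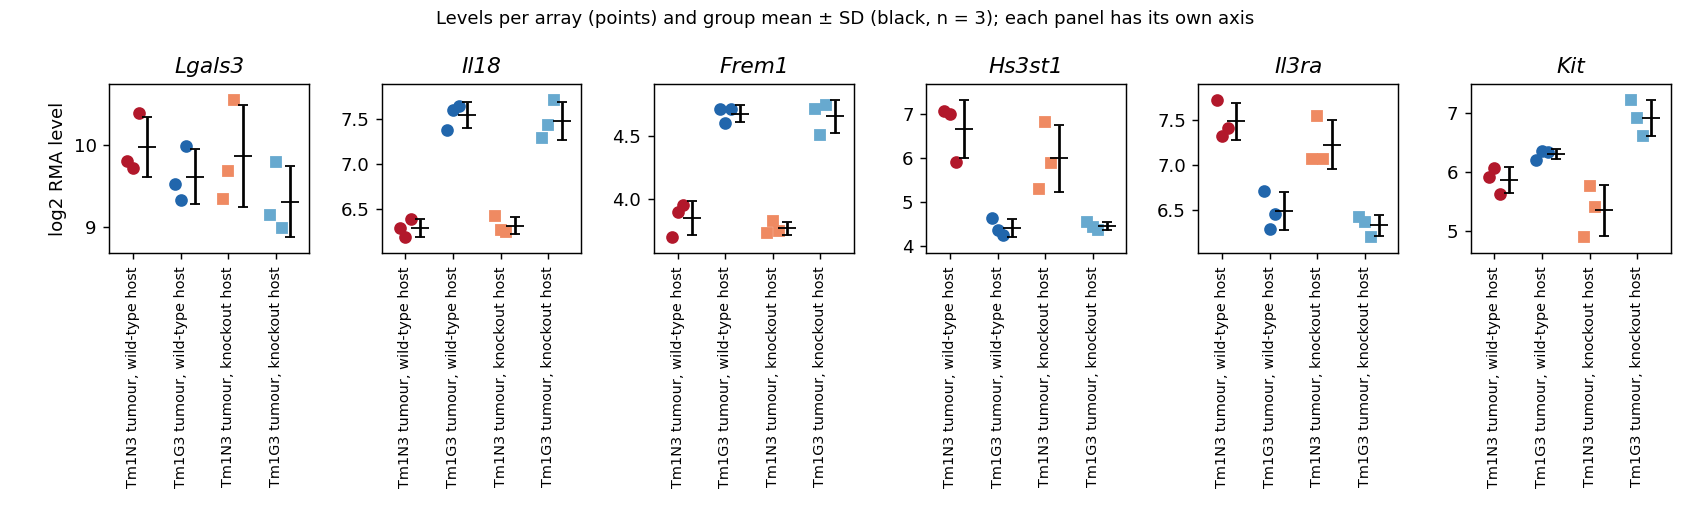
Log2 RMA levels of Lgals3, Il18, Frem1, Hs3st1, Il3ra and Kit in the 4 groups, with 1 point per array and the group mean ± SD in black (n = 3); each panel has its own vertical axis. Lgals3 groups overlap, with means from 9.31 to 9.97, whereas Il18 and Frem1 lie lower in every Tm1N3 array than in any Tm1G3 array.

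The comparison of Tm1N3 with Tm1G3 tumours in wild-type hosts asks what the tumour line changes where the host makes galectin-3. Hs3st1, a heparan sulfate 3-O-sulfotransferase, was 4.72-fold higher in Tm1N3 tumours, at a log2 level of 6.66 ± 0.65 against 4.42 ± 0.20 (SD, n = 3 each). Mcoln3, a cation channel of endosomes and lysosomes, was 2.33-fold higher, Il3ra, the interleukin-3 receptor alpha chain, 2.00-fold, and the cytokine gene Il17b 1.94-fold. The inflammatory cytokine gene Il18 was 2.37-fold lower in Tm1N3 tumours, at 6.29 ± 0.10 against 7.54 ± 0.14 (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.000593), and Frem1, a basement membrane protein gene, was 1.78-fold lower (limma, adjusted p = 0.000901).

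In all, 11 of 1246 probe sets passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 5 higher and 6 lower in Tm1N3 tumours, and 163 had an unadjusted p under 0.05 where 62.3 were expected by chance. The other 5 were the galactosyltransferase gene B3galt4 (log2 difference 0.37 ± 0.07, SE), Il17rd (-0.71 ± 0.13), which encodes a receptor-like inhibitor of fibroblast growth factor signalling, Bmp15 (-0.44 ± 0.07), Mgat3 (-0.43 ± 0.08), which adds the bisecting N-acetylglucosamine of N-glycans, and the sialyltransferase gene St6galnac6 (-0.42 ± 0.08). In all 11 the 3 Tm1N3 arrays lay apart from the 3 Tm1G3 arrays, which chance gives for 10% of probe sets taken at random, whereas these were chosen by p in the same comparison, which favours such a gap. Bmp15 was dim, at the 16.2 percentile of mean level. Frem1 was nearly so, at the 25.6 percentile. Its mean in Tm1N3 tumours of wild-type hosts, 3.85, lay below 4.22, the mean level that bounds the lowest 25% of probe sets. The Il17rd mean there, 4.19, did so too. In Tm1N3 tumours of knockout hosts the means were 3.77 for Frem1 and 4.10 for Il17rd, also below that bound. Il18 and Frem1 passed with any 1 of the 12 arrays left out, Mcoln3 in 11 of the 12 fits, Il3ra in 7, Hs3st1 in 6, Il17b, B3galt4, Il17rd and Bmp15 in 5 each, Mgat3 in 4 and St6galnac6 in 3. The count was 4, 6 and 5 without WT_Tm1N3 replicates 1, 2 and 3, 5 and 2 without WT_Tm1G3 replicates 2 and 3, 17 and 21 without KO_Tm1N3 replicates 2 and 3, and 19, 3 and 4 without KO_Tm1G3 replicates 1, 2 and 3, and it was 3 when only the arrays of these 2 groups were fitted. Quantile normalizing the deposited values again gave 10 higher and 5 lower, and centring each array on its median gave 4 higher and 2 lower.

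Among the gene lists fixed in advance, 29 of 33 measured cytokines and chemokines had negative log2 differences in wild-type hosts, that is, lower values in Tm1N3 tumours, with a median of -0.18. Of the 33, Il18 fell and 32 did not pass, and the same count held when adjusted over the list alone. Il1b (-1.53 ± 1.03, SE), Cxcl2 (-1.36 ± 1.26) and Ccl3 (-1.02 ± 0.72) had large but variable differences that did not pass. The list passed camera at a preset correlation (adjusted p = 0.0134 over 9 lists), a call lost with an estimated correlation (p = 0.251, adjusted p = 0.850), without WT_Tm1G3 replicate 1 (camera adjusted p = 0.519), without WT_Tm1N3 replicate 2 (0.211) and without WT_Tm1N3 replicate 1 (0.0546). Beside this list, all 5 macrophage and all 5 neutrophil markers had negative differences, with medians of -0.51 and -0.67, and none passed.

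None of the 9 measured galectin genes passed over all probe sets, and 1, Lgalsl (-0.63 ± 0.13, SE), passed when adjusted over the list alone. Of 16 angiogenic factors none passed over all probe sets, and when adjusted over the list alone Vegfc (0.26 ± 0.07) was higher and Fgf1 (-0.55 ± 0.13) lower, while Vegfa (0.62 ± 0.22) did not pass. Among 7 fibroblast and matrix genes none passed over all probe sets and Fbln5 (0.72 ± 0.16) was higher when adjusted over the list alone. No member of the endothelial (5), macrophage (5), neutrophil (5), T and NK cell (8) or adhesion (8) lists passed either way.

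The same comparison in knockout hosts asks what the tumour line changes where the host lacks galectin-3. Slc35f1, a gene of the solute carrier 35 family, was 3.94-fold lower in Tm1N3 tumours, at 5.52 ± 0.35 against 7.50 ± 0.34 (SD, n = 3 each). Kit, the stem cell factor receptor of melanocytes and mast cells, was 2.93-fold lower, at 5.36 ± 0.43 against 6.91 ± 0.30 (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.00635). Il18 was again lower, 2.23-fold, as were Il17rd (1.89-fold), Frem1 (1.85-fold), Havcr2, which encodes the immune checkpoint receptor TIM-3 (1.42-fold), and the interleukin-17 receptor gene Il17rc (1.41-fold). Il3ra was 1.86-fold higher and B3galt4 1.27-fold higher in Tm1N3 tumours.

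These 9 were the probe sets past an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2 higher and 7 lower, and 118 had an unadjusted p under 0.05. In all 9 the groups lay apart, which the choice by p again favours. Il18, Frem1, Il17rd, Kit and Havcr2 passed with any 1 of the 12 arrays left out, Slc35f1 in 9 of the 12 fits, Il3ra in 5 and B3galt4 and Il17rc in 2 each, and the count was 5 without KO_Tm1G3 replicate 1 and 5 without KO_Tm1G3 replicate 2. It was 4 when only the arrays of these 2 groups were fitted. Il3ra, B3galt4 and Il17rc no longer passed when arrays of the same number within a line were fitted as a random block, chosen after seeing the data.

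Of the fixed lists in knockout hosts, none passed camera (smallest adjusted p = 0.534 over 9 lists). Il18 fell and the other 32 cytokines and chemokines did not pass. When adjusted over the list alone, the galectin genes Lgals7 (0.68 ± 0.21, SE) and Lgalsl (-0.42 ± 0.13), the endothelial adhesion gene Icam2 (-0.51 ± 0.12) and the angiogenic factor Fgf1 (-0.51 ± 0.13) passed, as did the T cell chemokine gene Ccl5 (-0.76 ± 0.17) and Fbln5 (0.80 ± 0.16), and over all probe sets none of them did. No macrophage, neutrophil or adhesion gene passed either way.

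The 2 hosts shared 5 calls, all in the same direction: Il3ra and B3galt4 higher and Il18, Frem1 and Il17rd lower in Tm1N3 tumours. Independent lists of these lengths would share 0.0417 in the same direction. Across probe sets the log2 differences correlated with r = 0.633, or 0.468 without the probe sets called in the averaged comparison; genes are not independent replicates. The group means compared share no arrays, but both comparisons took each probe set's spread from the same fit. The SE of Il18, for example, was 0.1134 in each host. A small spread thus favours a call in both hosts, which raises the overlap above that of independent lists. Same-numbered arrays of the 2 hosts also deviated together within a line, so neither the overlap nor r is that of independent comparisons.

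Averaged over hosts, 53 of 1246 probe sets differed between the lines (limma, Benjamini-Hochberg adjusted p under 0.05), 16 higher and 37 lower in Tm1N3 tumours. All 53 had the same sign in both hosts, and in 37 the 6 Tm1N3 arrays lay apart from the 6 Tm1G3 arrays, which chance gives for 0.2165% of probe sets taken at random. The choice by the averaged difference favours both. The largest differences were Hs3st1 (log2 difference 1.89 ± 0.26, SE), Il3ra (1.93-fold), Mcoln3 (1.91-fold) and Fbln5, an elastic fibre gene (1.70-fold), on the higher side, and Slc35f1 (3.14-fold), Il18 (2.30-fold), Kit (1.99-fold) and Frem1 (1.81-fold) on the lower side. Il18 and Frem1 had the smallest adjusted p, 2.20e-05 each (limma, Benjamini-Hochberg).

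**Figure D3:**
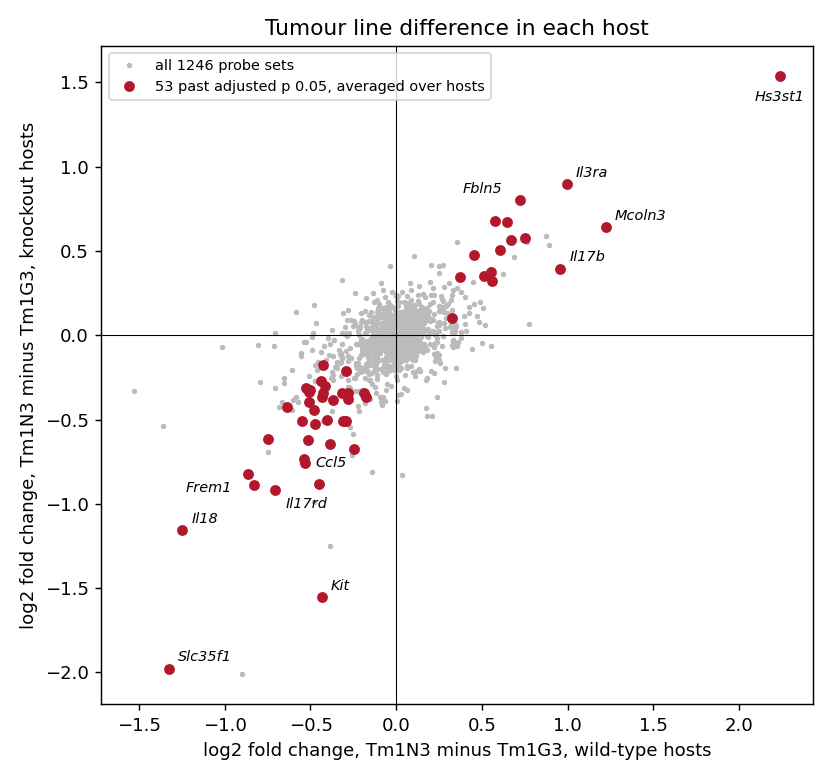
Log2 fold change of Tm1N3 minus Tm1G3 in wild-type hosts (horizontal axis) and in knockout hosts (vertical axis) for 1246 probe sets in grey, with the 53 past the threshold averaged over hosts in red. The 53 lie only where both differences have the same sign, and Kit, at -0.44 in wild-type and -1.55 in knockout hosts, has the smaller difference in wild-type hosts.

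Genes of glycan synthesis and breakdown were among the averaged differences. Fut11, a fucosyltransferase gene (log2 difference 0.61 ± 0.10, SE), B3galt4 (0.36 ± 0.05), the hyaluronan synthase gene Has3 (0.21 ± 0.05) and the lysosomal enzyme genes Galc (0.55 ± 0.09) and Idua (0.43 ± 0.09) were higher in Tm1N3 tumours. The galactosyltransferase genes B4galt4 (-0.57 ± 0.11) and B3galt5 (-0.46 ± 0.10), the sialyltransferase genes St3gal3 (-0.41 ± 0.09) and St6galnac6 (-0.36 ± 0.06), Mgat3 (-0.40 ± 0.06), Galnt10 (-0.45 ± 0.08) and Hpse, which encodes the heparan sulfate cleaving enzyme heparanase (-0.46 ± 0.10), were lower. So were the heparan sulfate proteoglycan genes Sdc2 (-0.52 ± 0.09) and Gpc6 (-0.41 ± 0.09) and the lysosomal genes Arsb (-0.38 ± 0.08), Galns (-0.33 ± 0.06) and Gm2a (-0.25 ± 0.06). Lists of these families were drawn up after the gene names on the array had been seen and before any test; 19 sialyltransferases gave 0 higher and 2 lower, 17 galactosyltransferases 1 higher and 2 lower, 27 heparan sulfate genes 1 and 1, and 26 lysosomal genes 2 and 3. No list of this family passed camera in this comparison (smallest adjusted p = 0.174 over 28 lists).

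Genes of receptors and secreted factors were among them too. Of 37 interleukin receptor genes, a list drawn up after the gene names had been seen, Il3ra (0.95) rose, 3 fell and 33 did not pass (camera adjusted p = 0.970). Lower in Tm1N3 tumours were Il17rd (-0.81 ± 0.09, SE), Il12rb1 (-0.64 ± 0.13) and Il17rc (-0.45 ± 0.07), and so were the interferon gamma receptor gene Ifngr2 (-0.33 ± 0.06), the T cell chemokine gene Ccl5 (-0.65 ± 0.12), the growth factor gene Fgf1 (-0.53 ± 0.09), Havcr2 (-0.40 ± 0.05) and Tenm4 (-0.50 ± 0.09), whose other probe set did not pass (-0.41). Il17b (0.68 ± 0.12), Podxl2, a sialomucin that binds selectins (0.66 ± 0.13), the adhesion gene Mcam (0.66 ± 0.15), Angptl2 (0.46 ± 0.07), the TGF beta receptor gene Tgfbr1 (0.46 ± 0.10) and Zkscan3 (0.44 ± 0.10) were higher. Of the 9 galectin genes, Lgals7 (0.63 ± 0.15) rose, Lgalsl (-0.53 ± 0.09) fell and 7 did not pass, among them Lgals3 (0.46 ± 0.23). Of 5 endothelial markers Icam2 (-0.40 ± 0.08) fell and 4 did not pass, and of 16 angiogenic factors Fgf1 fell and 15 did not pass, with Vegfa at 0.49 ± 0.16 and Vegfc at 0.20 ± 0.05, the last higher when adjusted over the list alone. Of 33 cytokines and chemokines Il18 fell and 32 did not pass, of 7 fibroblast and matrix genes Fbln5 rose and 6 did not pass, of 8 T and NK cell markers Ccl5 fell and 7 did not pass, and no macrophage, neutrophil or adhesion gene passed.

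No fixed list passed camera in the averaged comparison (smallest adjusted p = 0.0778, the cytokines and chemokines, 28 of 33 negative), though this list passed after quantile normalizing again (camera adjusted p = 0.0328) and with each array centred on its median (0.0420). With an estimated correlation on the deposited values it had p = 0.336 and adjusted p = 0.932. All 5 macrophage markers were negative beside it, with a median of -0.37. Among the largest differences Lgals7 passed in 2 of the 12 fits with 1 array left out, Gpc6 in 6, Tgfbr1 and Zkscan3 in 7, Podxl2 in 9 and Il12rb1 in 10. The count of 53 became 32 without KO_Tm1G3 replicate 2, and quantile normalizing again turned the division from 16 higher and 37 lower to 29 higher and 28 lower, with 42 probe sets shared. With arrays of the same number within a line as a random block, chosen after seeing the data, 40 passed, all among the 53, and of the genes named Icam2, Gm2a, Mcam, Il12rb1, Zkscan3, Has3, Lgals7, B3galt5 and Hpse no longer did (limma, Benjamini-Hochberg adjusted p from 0.0545 to 0.0756).

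The comparison of knockout with wild-type hosts in Tm1N3 tumours asks what galectin-3 of the host changes where, per the labels, the tumour cells express it. None of 1246 probe sets passed in limma (smallest Benjamini-Hochberg adjusted p = 0.963), and 54 had an unadjusted p under 0.05 where 62.3 were expected. The smallest p values belonged to the C-type lectin genes Cd209b (log2 difference, knockout minus wild-type, -0.39 ± 0.09, SE) and Cd209e (-0.24 ± 0.06), the lysosomal membrane gene Lamp2 (-0.32 ± 0.10), Has3 (-0.22 ± 0.07) and the chemokine receptor gene Cxcr5 (0.16 ± 0.05), and none of these passed. Other probe sets of Cd209b (-0.09) and Lamp2 (-0.14) gave smaller differences.

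No fixed list passed camera for this comparison (smallest adjusted p = 0.530, the endothelial markers, all 5 negative with a median of -0.22), and no member of the 9 lists passed either over all probe sets or when adjusted over the list alone. Vegfa differed by -0.42 ± 0.22 (SE) and Tgfb1 by 0.37 ± 0.19. Blocking on replicate number left the count at 0. Of the lists of the array's own families none passed (smallest camera adjusted p = 0.202, the lysosomal glycan breakdown genes, 22 of 26 negative), but the lysosomal list passed after quantile normalizing again (camera adjusted p = 0.00169), against p = 0.352 and adjusted p = 0.998 with an estimated correlation on the deposited values. Leaving out WT_Tm1N3 replicate 3 or KO_Tm1N3 replicate 2 gave 1 such list past camera.

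In Tm1G3 tumours the same comparison asks about host galectin-3 where, per the labels, that of the tumour cells is silenced. Again no probe set passed in limma (smallest Benjamini-Hochberg adjusted p = 0.531), and 77 had an unadjusted p under 0.05 against 62.3 expected. Igfbp4, which encodes an insulin-like growth factor binding protein, had the smallest p, at 9.98 ± 0.07 in knockout and 9.57 ± 0.08 in wild-type hosts (SD, n = 3 each), a log2 difference of 0.41 ± 0.08 (SE), and its other probe sets gave 0.26 and 0.34. Other genes with small p values were Bmp15 (-0.28 ± 0.07), Cd209e (-0.24 ± 0.06) and the nucleotide sugar transporter family gene Slc35b1 (0.34 ± 0.09). None of these passed.

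No fixed list passed camera in Tm1G3 tumours (smallest adjusted p = 0.0872, the cytokines and chemokines, 25 of 33 negative in knockout hosts), though this list passed with each array centred on its median (camera adjusted p = 0.0206). With an estimated correlation on the deposited values it had p = 0.343 and adjusted p = 0.819. All 5 neutrophil markers were negative beside it, with a median of -0.61, and no list member passed either way. The angiogenic factors Tgfb1 (0.47 ± 0.19, SE), Angpt2 (0.40 ± 0.15) and Tgfb3 (0.36 ± 0.13) were among those with positive differences that did not pass. Among the 28 lists of the array's own families, 19 of 25 genes of N-glycan precursor synthesis and transfer had positive differences, among them Rpn1 (0.50 ± 0.16), Alg12 (0.29 ± 0.10) and Alg8 (0.28 ± 0.11), and none of the 25 passed. That list passed camera (adjusted p = 0.0119), a call lost with an estimated correlation (p = 0.170, adjusted p = 0.825), without WT_Tm1G3 replicate 3 (adjusted p = 0.212), without KO_Tm1G3 replicate 2 (0.0803) and without WT_Tm1G3 replicate 1 (0.0539), and with the macrophage mean as a covariate, chosen after seeing the data (0.158).

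Averaged over tumour lines, no probe set differed between hosts in limma (smallest Benjamini-Hochberg adjusted p = 0.226), and 78 had an unadjusted p under 0.05. Cd209e (log2 difference -0.24 ± 0.05, SE) and Cd209b (-0.32 ± 0.06) had the smallest p, lower in knockout hosts, followed by the mannose-binding lectin gene Mbl1 (-0.17 ± 0.04), Bmp15 (-0.20 ± 0.05) and Igfbp4 (0.21 ± 0.06). None of these passed, and the other probe sets gave -0.05 for Cd209b and 0.06 and 0.14 for Igfbp4. Some were dim in knockout hosts, below 4.22, the mean level that bounds the lowest 25% of probe sets. In Tm1G3 tumours of knockout hosts the means were 4.14 for Mbl1, 3.81 for Bmp15 and 4.18 for Cd209e. No fixed list passed camera (smallest adjusted p = 0.336). The macrophage marker mean was 6.63 in knockout against 6.74 in wild-type hosts in Tm1N3 tumours, and 6.96 against 7.21 in Tm1G3 tumours. Arrays of the 2 hosts overlapped in both lines, so no direction is drawn from these means. In Tm1G3 tumours the wild-type mean leaned on replicate 1, at 7.95 against 6.55 and 7.14 in replicates 2 and 3. Knockout arrays of that line ran from 6.77 to 7.25. The neutrophil mean was 5.96 against 5.91 in Tm1N3 and 6.07 against 6.62 in Tm1G3 tumours. The N-glycan precursor list passed (camera adjusted p = 0.0334, 19 of 25 positive), a call lost with an estimated correlation (p = 0.2035, adjusted p = 0.879), after quantile normalizing again (adjusted p = 0.438) and with the macrophage covariate (0.2345). It was also lost without WT_Tm1N3 replicate 1 (0.0883) or 3 (0.420), WT_Tm1G3 replicate 1 (0.0745) or 3 (0.254), KO_Tm1N3 replicate 1 (0.0746) or 2 (0.152), and KO_Tm1G3 replicate 1 (0.0888) or 2 (0.0965).

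The interaction asks whether the tumour line difference was the same in both hosts. No probe set passed in limma (smallest Benjamini-Hochberg adjusted p = 0.996), and 35 had an unadjusted p under 0.05 against 62.3 expected. Kit, called in knockout hosts only, had a line difference of -1.55 there and -0.44 in wild-type hosts, and the difference of the differences, -1.12 ± 0.30 (SE), did not pass. The other genes with the smallest p were Igfbp4 (-0.39 ± 0.10), the acid ceramidase gene Asah1 (-0.36 ± 0.11), Cd72, a surface protein gene of B cells, (-0.71 ± 0.23) and Rpn1 (-0.66 ± 0.23), and none passed.

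No fixed list passed camera for the interaction (smallest adjusted p = 0.0786, the endothelial markers, all 5 negative with a median of -0.42). Centring each array on its median gave that list an adjusted p of 0.0231, and with an estimated correlation its adjusted p was 0.724. Among the lists of the array's own families, the lysosomal glycan breakdown genes passed (camera adjusted p = 0.0443): 21 of 26 were negative with a median of -0.11, and no single member passed. That call was lost with an estimated correlation (p = 0.248, adjusted p = 0.798) and with replicate number as a block (adjusted p = 0.0628), with each array centred on its median (0.0572) and with the mean over a gene's probe sets (0.0624). It was also lost without WT_Tm1N3 replicate 2 (0.503), WT_Tm1G3 replicate 3 (0.398), KO_Tm1N3 replicate 1 (0.355) or 3 (0.0704), and KO_Tm1G3 replicate 1 (0.219) or 2 (0.0775).

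Markers of other cell types varied between tumours within every group. The mean of the 5 macrophage markers ranged from 6.01 in KO_Tm1N3 replicate 1 to 7.95 in WT_Tm1G3 replicate 1, with group means from 6.63 in Tm1N3 tumours of knockout hosts to 7.21 in Tm1G3 tumours of wild-type hosts. The neutrophil marker mean was 5.91 in Tm1N3 and 6.62 in Tm1G3 tumours of wild-type hosts, against 5.96 and 6.07 in knockout hosts, and no macrophage or neutrophil marker passed in any comparison. With the macrophage mean as a covariate, chosen after seeing the data, 94 probe sets passed in the averaged line comparison, 52 of them among the 53, and the cytokine list in wild-type hosts no longer passed (camera adjusted p = 0.461).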

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

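Of the tests in this part, the covariate fit, the weighing by an estimated correlation and the divisions that keep numbered pairs together were chosen after seeing the data, and the gene list was drawn up after the array's gene names had been seen.

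The tumour line difference in lysosomal glycan breakdown genes differed between the 2 hosts in a test of the interaction itself at a preset correlation (camera adjusted p = 0.0443 over 28 lists), but not with an estimated correlation (p = 0.248, adjusted p = 0.798). The median line difference was 0.06 in wild-type and -0.06 in knockout hosts, 21 of 26 genes had a negative interaction, and the median was -0.11 on the log2 scale, with Asah1 (-0.36 ± 0.11, SE), Aga (-0.37 ± 0.14), Sgsh (-0.28 ± 0.13) and Gaa (-0.33 ± 0.16) in the lead. A difference in macrophage content, since macrophages are rich in lysosomes, was argued against: with the macrophage marker mean as a covariate the median was 1.085 times that without it (camera adjusted p = 0.0407). Content of other cell types was not tested. All 5 endothelial markers had a negative interaction, with a median of -0.42. The neutrophil mean was 5.91 in Tm1N3 against 6.62 in Tm1G3 tumours of wild-type hosts, and 5.96 against 6.07 in knockout hosts. Genes that vary together between tumours remain a candidate explanation, as the estimated correlation, which allows for this, ended the call. No list passed with it in any comparison, however, so the loss cannot decide for this explanation. The call was also lost, for causes that were not tested, with replicate number as a block (0.0628), with each array centred on its median (0.0572, the median interaction still -0.10), with the mean over a gene's probe sets (0.0624) and without WT_Tm1N3 replicate 2 (0.503), WT_Tm1G3 replicate 3 (0.398), KO_Tm1N3 replicates 1 (0.355) or 3 (0.0704), or KO_Tm1G3 replicates 1 (0.219) or 2 (0.0775), in a range from 0.00239, and a biological difference between the hosts stays open and untested.

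Other divisions of the arrays were compared with the real ones for every count of probe sets. For the tumour line averaged over hosts, the real division gave the largest count of 100 divisions, 1 of which gave as many: 53 against 13 at most in the others. That comparison treats the 12 arrays as independent, whereas same-numbered arrays of the 2 hosts deviated together within a line. With these pairs kept together and fitted as a random block, the real division gave 40 and the others at most 2, and 10 divisions are too few for a share under 0.05. In wild-type hosts the real division gave 11 and the 9 others at most 0, with 1 of 10 as large, and in knockout hosts 9 and at most 0, with 1 of 10, again too few for such a share. For the hosts in Tm1N3 and Tm1G3 tumours the real count was 0 and the others gave at most 1 and 0, those that part all 3 numbered pairs at most 0. For the host average and the interaction it was 0 too, and the others gave at most 17 and 61. Divisions for the host average stayed within each line. The 17 was the highest of the other divisions, whose median was 0, and whether it reflects some structure of the samples was not tested. For the interaction all 12 labels were shuffled, so a division can line up with the tumour line. The 61 thus cannot be told apart from the line difference. A count of 0 is reached by every division, here 10 of 10 and 100 of 100, so these comparisons say nothing about chance.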

How the results depend on the processing

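Of the tests in this part, those with the macrophage covariate, without the 2 arrays that correlated least and with a block or random block within each line were chosen after seeing the data. Named genes past the threshold gave 44 results with 987 values under alternatives; none turned in direction and 169 no longer passed. The tumour line counts moved most. In wild-type hosts the count of 11 became 6 with each array centred on its median, 48 with array weights and 3 with only the arrays compared, and 46 with the macrophage mean as a covariate and 24 without the 2 arrays that correlated least with the rest. It was 2 to 21 with 1 array left out: 4, 6 and 5 without WT_Tm1N3 replicates 1, 2 and 3, 5 and 2 without WT_Tm1G3 replicates 2 and 3, 17 and 21 without KO_Tm1N3 replicates 2 and 3, and 19, 3 and 4 without KO_Tm1G3 replicates 1, 2 and 3. In knockout hosts 9 became 55 with array weights, 4 with only the arrays compared, 21 with the covariate and 5 to 13 with 1 array left out, 5 without KO_Tm1G3 replicate 1 and 5 without KO_Tm1G3 replicate 2. Averaged over hosts 53 became 131 with array weights, 94 with the covariate and 32 (without KO_Tm1G3 replicate 2) to 63 with 1 array left out. Fits with 1 array left out or with only the arrays compared hold fewer arrays, but what moved the counts was not tested. The host and interaction counts were 0 under every alternative run.

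Lgals3 passed under no alternative. Its host difference in Tm1N3 tumours, -0.11, turned to 0.10 without WT_Tm1N3 replicate 3 and 0.15 without KO_Tm1N3 replicate 1, with a range of -0.45 to 0.15 over the arrays left out. Its interaction, 0.20, turned to -0.19 with array weights, -0.10 without the 2 arrays that correlated least and -0.15 without KO_Tm1N3 replicate 3, with a range of -0.15 to 0.45 over the arrays left out. The cause was not tested.

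Of the fixed lists, the 1 past camera in wild-type hosts became 0 with an estimated correlation, 0 with fry, and 0 (without WT_Tm1N3 replicate 1 or 2 or WT_Tm1G3 replicate 1) to 2 (without WT_Tm1G3 replicate 2). In knockout hosts, and for the host in Tm1N3 tumours, 0 became 3 without KO_Tm1N3 replicate 3 and stayed 0 without any other array. For the host in Tm1G3 tumours 0 became 2 without WT_Tm1G3 replicate 2, 3 without WT_Tm1G3 replicate 3, 1 without KO_Tm1G3 replicate 1 and 1 without KO_Tm1G3 replicate 2, and 2 with the macrophage covariate. With 1 array left out the line average gave 0 to 2 lists, the host average 0 to 2 and the interaction 0 to 4, highest without KO_Tm1N3 replicate 3, KO_Tm1N3 replicate 3 and WT_Tm1G3 replicate 3, and with the covariate the line average gave 1 and the interaction 1. Of the 28 lists of the array's own families, with 1 array left out 0 to 2 passed for the line in wild-type hosts (2 without WT_Tm1N3 replicate 1), 0 to 1 for the host in Tm1N3 tumours, 0 to 2 for the host in Tm1G3 tumours (2 without KO_Tm1N3 replicate 1 or KO_Tm1G3 replicate 3), 0 to 1 for the host average and 0 to 3 for the interaction (3 without KO_Tm1G3 replicate 3), and 0 in the others.

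Replicate number as a block gave 13 calls in wild-type and 13 in knockout hosts, 50 for the line average and 0 for the hosts and the interaction; 4 of 6 arrays of the wild-type and 1 of 6 of the knockout line comparison correlated best with their own number, a hint from the data only. A replicate block within each line gave 0 for every host comparison. Fitted as a random block, the same pairs gave 15 calls in wild-type and 6 in knockout hosts, 40 for the line average, all among the 53, and 0 elsewhere. Of the 50 calls with replicate number as a block 46 were among the 53; that block moved no count by more than 1.5 times and changed no list call but the lysosomal one. Signal over background could not be assessed.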

Other observations

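All tests in this part, the covariate fit included, were chosen after seeing the data.

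The widest differences between these tumours lay within groups, not between them. Of the variance left within groups, 51.0% fell on 1 axis, led by the chemokine genes Cxcl2 (within-group SD 1.76 on the log2 scale) and Ppbp (log2 4.35 to 8.80 over the 12 arrays), Il1b (5.92 to 11.1), the myeloid lectin gene Clec4d (5.75 to 9.02), the platelet chemokine gene Pf4 (7.95 to 11.2) and the proteoglycan gene Srgn (7.49 to 10.8). Cxcl12 (5.17 to 8.09), the fibroblast genes Dcn (7.47 to 9.91), Lum (5.33 to 7.72) and Pdgfra (5.62 to 7.96), and the macrophage genes Adgre1 (5.07 to 7.98), Csf1r (6.55 to 8.55) and Ccr2 (5.53 to 7.43) went the same way. Fgf21 (5.35 to 8.33), Rab7 and Lgals7 went the other way. In each group 1 array lay above 0 on this axis: replicate 3 in Tm1N3 and replicate 1 in Tm1G3 tumours, in both hosts. The arrays of both hosts thus lay on the same side of 0 in all 6 sets of a line and a number. That rests on these single arrays alone. The pairs were also taken from the same deviations, so it gives them no separate support.

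A candidate explanation, which these values do not decide, is that the myeloid and stromal cell content of the tumours varied: the means of the fixed macrophage and fibroblast lists, as deviations from group means over 12 arrays, correlated with r = 0.871 (exact permutation within groups, p = 0.01003, adjusted p = 0.0276 over 11 relations; rho = 0.902, p = 0.00309, adjusted p = 0.0255; r = 0.917 without the 2 arrays farthest out), but Dcn, Lum and Pdgfra of the one list and Adgre1, Csf1r and Ccr2 of the other were among the genes that led the axis, so this restates it. Those p values also treat the arrays as independent, whereas with same-numbered arrays of a line kept together exact permutation gave p = 0.0556 for r and 0.0278 for rho (adjusted p = 0.0833 each over 9 relations), and 0.0278 is the smallest that 36 orders can give. A lower share of tumour cells, which would raise all other types alike, stays open: slopes on the macrophage mean were higher for neutrophil than for endothelial markers by 0.772 (95% interval 0.0762 to 1.47), for fibroblast genes than for endothelial markers by 0.412 (-0.00951 to 0.833) and for fibroblast genes than for T and NK cell markers, most of them dim, by 0.634 (0.362 to 0.907), but over the means of the 6 sets the intervals were -0.00887 to 1.37, -0.325 to 1.27 and 0.215 to 1.15. With 1 array left out the 0.772 ran from 0.341 (without WT_Tm1G3 replicate 1) to 1.12 (without KO_Tm1N3 replicate 3), and its interval held 0 in 5 of the 12 fits: without WT_Tm1N3 replicate 1 or 3, WT_Tm1G3 replicate 2, KO_Tm1N3 replicate 2 or KO_Tm1G3 replicate 2. A shared replicate number is, by the titles, a shared rank of the arrays' own numbers within their groups. Whether it stands for anything more stays open too. RNA quality was not tested, nor was any biological explanation other than cell content. The axis was taken from deviations from group means, so by construction it could not follow the groups.

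Lgals3 differed little between lines and hosts, and it may be that myeloid content hides a line difference: with the macrophage mean as a covariate the averaged line difference was 0.64 ± 0.20 (SE) against 0.46 ± 0.23 without it. After Benjamini-Hochberg adjustment it did not pass (limma, adjusted p = 0.0890, in a range from 0.0890 to 0.599 over the alternatives), nor with the sets as a random block beside the covariate (limma, adjusted p = 0.112). A swap of single arrays between lines was argued against, since the lines lay 2.48 apart on PC2, which was chosen after it was seen to part them. An exchange of the 2 line names on all arrays would give the same gap, so it was not tested. Lgals3 RNA from host myeloid cells that knockout hosts lack stays open: within groups Lgals3 followed the macrophage mean with r = 0.532 in wild-type hosts (n = 6, exact permutation p = 0.361, rho = 0.771, p = 0.167) and r = 0.700 in knockout hosts (n = 6, exact permutation p = 0.278, rho = 0.714, p = 0.278), where r became -0.212 without the 2 arrays farthest out and so rests on them. Over all 12 arrays r was 0.624 (exact permutation p = 0.0957, adjusted p = 0.150) and rho 0.727 (p = 0.0239, adjusted p = 0.0658), or p = 0.167 for r and 0.0278 for rho with the sets kept together (adjusted p = 0.214 and 0.0833), with r = 0.575 without the 2 arrays farthest out.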
